A study of Mus musculus with 3 samples.

How the data were processed

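Single-cell RNA libraries were made with Chromium 3' chemistry (version 3) from the lungs of MMTV-HER2/Neu mice, which carry the rat homologue of HER2 under a mammary promoter and form mammary tumours. Each of the 3 groups holds 1 library: CD45-negative HER2-negative lung cells and CD45-negative HER2-positive lung cells from mice of 14 to 18 weeks, and CD45-negative HER2-positive lung cells from tumour-bearing mice older than 20 weeks. The submitters call the HER2-positive cells disseminated cancer cells (DCCs). They are called here the early HER2-negative, early HER2-positive and late HER2-positive libraries. With 1 library per group, stage, age and animal cannot be separated from library between the HER2-positive groups, nor the sort from library between the early groups, so no test between groups was made, and no p-value or standard error is given.

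The deposited values are unnormalised counts of unique molecular identifiers (UMIs) per gene and barcode. The matrices were written by software version 3.1.0, per the file headers, and the genome build is mm10, per the submitters' processing notes. The aligner and the annotation release are not given in the sources used here. The matrices are not filtered to cells: each file lists 6794880 barcodes and 27998 genes. Gene identifiers come from the files and coordinates from GENCODE on GRCm38/mm10.

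The choices of filters, cell type markers, gene lists, comparisons and the rule for named genes were made before the data were examined. A barcode was kept with at least 500 UMIs, at least 200 detected genes and under 25% of UMIs on mitochondrial genes. Doublets were scored per library with the Scrublet function of scanpy. Its automatic threshold marked 0.0454% of early HER2-negative, 0.0125% of early HER2-positive and 0.948% of late HER2-positive barcodes. Where it marked under 0.5%, the highest-scoring share (0.8% per 1000 kept barcodes) was removed instead, by a rule set in advance. This removed 350, 510 and 58 barcodes, so doublets were treated unevenly between the early and late libraries. Background RNA was described from barcodes with 1 to 100 UMIs.

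Kept cells were 6263, 7474 and 6060 in the early HER2-negative, early HER2-positive and late HER2-positive libraries. Total UMIs per file were 25610135, 49248126 and 54961019, of which 81.7%, 81.0% and 91.8% lay in kept cells. Median UMIs per cell were 3061, 4815.5 and 7975.5.

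Cells of the 3 libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering ran at resolution 1 on 15 exact nearest neighbours. Clusters were named "X-like" only from the fixed markers of 22 cell types. A name needed at least 3 markers at 50 CPM (counts scaled to a common library total) or more and 3-fold above the median of the other clusters, and a marker among the 10 leading genes. A cluster in which another class scored at least 0.5 of the first stayed unnamed. These naming thresholds were set after the data were seen. Of 32 clusters, 8 stayed unnamed, of which 23, 26, 29 and 30 showed markers of a pair of classes. Cluster 29 shared the leading genes of alveolar type 2-like cells and held 0, 59 and 23 cells in the early HER2-negative, early HER2-positive and late HER2-positive libraries. Cluster 30 shared those of endothelial-like cells and held 8, 35 and 28. Cluster 26, with alveolar type 1 and 2 genes, held 0, 49 and 73 cells. Cluster 23, led by Hhip, held 71, 67 and 6. Pericyte and smooth muscle markers were joined as mural, and club, secretory and basal airway markers as airway secretory or basal. Names are rebuilt here and need not match the submitters' own. Marker symbols missing or duplicated in the files, such as Gucy1a1, Trac and Ccl21a, were left out.

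Within all kept cells, or within a class of at least 50 cells in both libraries, raw counts were summed and expressed as CPM of the kept total. Intervals are at the 95% level: exact Poisson for CPM, exact conditional for ratios and Clopper-Pearson for shares. They cover counting error only, and understate the error where few cells hold most counts. A count of 0 is given with the limit of 3 counts. Shares of cells with proliferation or mixed-identity transcripts were taken after thinning each cell to 1000 UMIs. Genes sharing reads with near-identical copies (the haemoglobin genes, Lyz1 and Lyz2, the H2 genes) are uncertain.

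The 15 gene lists were summarised by the number of members at least 1.5-fold higher or lower among those with at least 10 counts, by the median log2 ratio, and by its percentile among 10000 random lists matched on mean expression. Named genes are those with at least 50 CPM in a library of the pair, without predicted models, ribosomal protein genes, mitochondrial genes and Erbb2. Of these the 10 highest and 10 lowest ratios were named over all cells and in alveolar type 2-like cells, and 5 and 5 in other classes. The extreme members of each list with at least 50 counts, the 11 study genes and cluster markers were named too. A few genes that this rule names are not reported here. The comparison of mammary-like with other late cells and its genes was chosen after the data were seen, as were the list counts within single clusters.

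The steps were tested on simulated data with the depth of each pair of libraries, on 27998 genes. For the early over the late HER2-positive library, the interval held the true ratio for 97.0% of 67 genes changed 1.5-fold, 97.0% of 67 changed 2-fold, 93.9% of 66 changed 4-fold and 95.5% of 15730 unchanged genes. A simulated 2-fold higher list had 14 of 15 members called higher, and its median at percentile 100. For the early HER2-positive over the early HER2-negative library, the same figures were 92.5%, 97.0% and 92.4% for the changed genes, 95.6% of 15334 unchanged genes, and 15 of 15 list members. The medians of the 14 unchanged lists spread over percentiles 0.93 to 99.43 in the first pair and 17.02 to 98.17 in the second. Of their measured members, 13 of 243 and 11 of 238 were called higher or lower.

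Alternatives were a minimum of 1000 UMIs, a mitochondrial limit of 10%, called doublets kept, Leiden resolutions of 0.5 and 2, 1000 variable genes, trimmed-mean scaling, equal weight per cell, 10% of each library taken off as background, a list minimum of 50 counts or none, thinning to 500 or 2000 UMIs, and 1 gene more or fewer per cell call. Added after the data were seen were the highest-scoring doublet share removed in all libraries, CPM without alveolar type 2 marker genes, and leaving out the cell with most counts of a gene. Over all cells, trimmed-mean scaling took 0.12 off the log2 ratios of the early over the late HER2-positive library. The amount taken off was -0.41 for the early HER2-positive over the HER2-negative library, which makes those ratios higher. Cell calls with intronic reads, splicing and the genotype of single cells were left out because the files hold no reads. Tools were Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.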

Results

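The data are 3 single-cell RNA libraries of sorted CD45-negative lung cells from MMTV-HER2/Neu mice, 1 per group. HER2-negative and HER2-positive cells came from mice before tumours are evident, and a further HER2-positive library came from older mice with primary tumours. Kept cells numbered 6263, 7474 and 6060, with 20928862, 39876130 and 50459514 UMIs. Every comparison below is between single libraries, with no replicate check.

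The cell types in the sorted libraries come first, because they set what any difference between libraries can mean. The sort was on HER2, the tumour-driving receptor, and on CD45, a leukocyte protein, so the shares are those of sorted cells and not of the lung. Cells with the genes of gas-exchange epithelium, vessel walls and airway made up most of both HER2-positive libraries. A cluster led by genes such as the milk protein genes of mammary epithelium held cells of the late HER2-positive library alone.

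Alveolar type 2-like cells were named from markers such as Lamp3 and the surfactant genes Sftpc and Sftpb. They were 47.3% of early HER2-positive cells (95% interval 46.1 to 48.4) and 63.6% of late ones (62.3 to 64.8). They were 0.814% of early HER2-negative cells, or 51 cells. Mural-like cells, which carry pericyte and smooth muscle genes such as Higd1b and Acta2, were 19.8% of early HER2-positive, 15.9% of late HER2-positive and 3.18% of HER2-negative cells. Endothelial-like cells (Cldn5, Cdh5) were 81.6% of the HER2-negative library, 21.3% of the early and 8.20% of the late HER2-positive library. Fibroblast-like cells were 11.6%, 2.89% and 0.957% in the same order. Alveolar type 1-like cells were 0.798%, 2.27% and 1.44%. Ciliated airway-like cells numbered 0, 84 and 122, and airway secretory or basal-like cells 1, 60 and 78. Unnamed clusters held 2.01%, 4.51% and 3.45% of cells. Among the named clusters, cluster 9 of the endothelial-like class was led by the interferon-induced gene Gbp4.

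**Figure D1:**
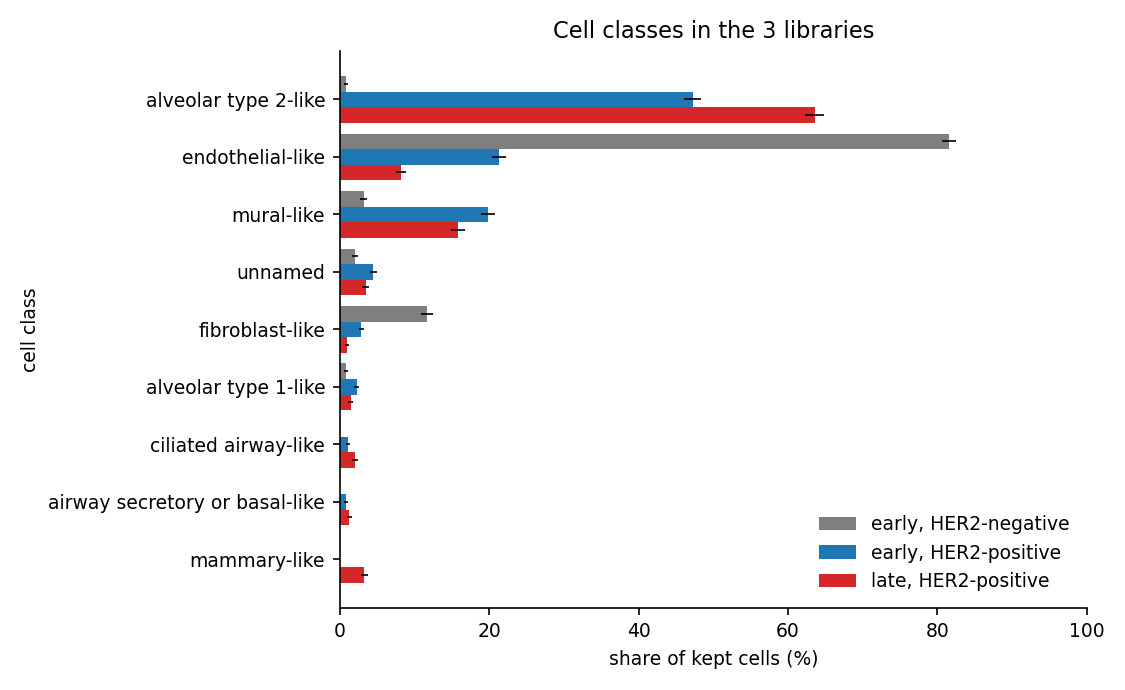
Share of kept cells in each class (x axis, percent) for each library; bars are single libraries and lines are exact 95% intervals for counting error only. The endothelial-like bar of 81.6% belongs to the early HER2-negative library, and the alveolar type 2-like bars of 47.3% and 63.6% to the HER2-positive libraries.

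Mammary-like cells were a single cluster of 196 late cells, 3.23% of that library (2.80 to 3.71). None of 7474 early HER2-positive cells fell in it, which allows a share of up to 0.0401%, and none of 6263 HER2-negative cells did. Their leading genes were the caseins Csn3, Csn1s1 and Csn1s2a and Lalba, which encode milk proteins, and Wfdc18, which is not counted among milk protein genes here. Erbb2, the mouse HER2 gene (ENSMUSG00000062312, chromosome 11, 98412470 to 98437716 on GRCm38/mm10), is the sort marker and serves as a label check. It stood at 17.4 CPM in HER2-negative cells (15.7 to 19.3), 19.7 in early HER2-positive cells (18.3 to 21.1) and 40.0 in late HER2-positive cells (38.3 to 41.8). In mammary-like cells it reached 294 CPM (278 to 311), and in the other late cells 16.8. Rat transgene transcripts are counted only as far as they map to the mouse gene.

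The mammary-like cells were set against the other late cells of the same library to describe what sets them apart. Most cell division, hypoxia and glycolysis genes were higher in them, and most mesenchymal genes lower. Gata3, a luminal mammary transcription factor (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034), was 64.8-fold higher (55.9 to 75.3), and Trps1 36.8-fold. Csn3 (ENSMUSG00000001622, chromosome 5, 87925579 to 87932665) was 1607-fold higher, and the epithelial adhesion gene Epcam 16.1-fold. The epithelial cadherin Cdh1 went the other way at 0.335 of the level in other late cells (0.295 to 0.380), as did the keratin gene Krt19 at 0.0376. Of the epithelial list, 13 of 23 members were higher and 6 lower. Of the mesenchymal list, 25 of 27 were lower and 0 higher, and the intermediate filament gene Vim stood at 12.8 CPM against 224. The basement membrane list had 17 of 19 lower. The other late cells include mural-like, endothelial-like and fibroblast-like cells, with Vim at 966, 1517 and 1708 CPM, so these ratios depend on that mix. In late alveolar type 2-like cells Vim was at 3.25 CPM, under the level in mammary-like cells. The lists were not compared with that class alone.

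Mki67, a gene of dividing cells, was at 124 CPM in mammary-like cells and 1.17 CPM in the other late cells. The mammary-like cells held 521 of its 575 late counts. All 24 G2 and M phase genes and 19 of 24 S phase genes were higher. After thinning, 20 of 193 mammary-like cells (10.4%, 6.45 to 15.6) had UMIs of at least 3 proliferation genes. In alveolar type 2-like cells of the late library 3 of 3832 did, and in those of the early HER2-positive library 1 of 3479. Hypoxia and glycolysis genes were higher for 12 of 16 members, led by Egln3, an oxygen sensor (408-fold), with the glucose transporter gene Slc2a1 at 10.3-fold. Dormancy-associated genes split, with 10 of 26 higher and 11 lower. Bhlhe41 was 3.53-fold higher (1.95 to 6.09), whereas Nr2f1 was at 0.0421 and Cdkn1a at 0.294 of the level in other late cells. The Nr2f1 ratio rests on mural-like cells in the comparison, which held 987 of its 1045 late counts. Late alveolar type 2-like cells held 0.116 CPM of Nr2f1 and mammary-like cells 0.949 CPM, from 4 counts each.

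**Figure D2:**
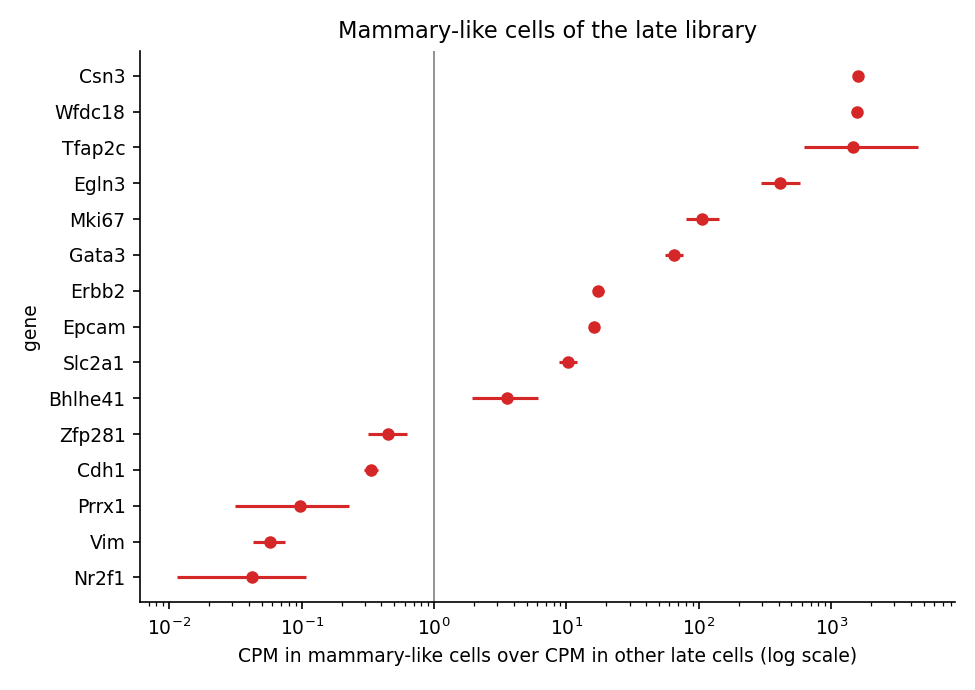
Ratio of CPM in the 196 mammary-like cells to CPM in the other cells of the late library (x axis, log scale) for selected genes; points are ratios and lines exact 95% intervals for counting error only. Csn3 and Wfdc18 lie above 1000-fold, and Zfp281, Cdh1, Prrx1, Vim and Nr2f1 lie below a ratio of 1.

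Zfp281 is the gene of a zinc finger transcription factor that the study follows in early spread and dormancy, and the question is how it differs between early and late HER2-positive cells. Over whole libraries its level was highest in HER2-negative cells and higher in early than in late HER2-positive cells. Within alveolar type 2-like, mural-like and endothelial-like cells, the early and late HER2-positive libraries differed by less than counting error. Zfp281 (ENSMUSG00000041483, chromosome 1, 136624901 to 136630053) stood at 38.9 CPM in the HER2-negative library (36.3 to 41.7), 23.2 in the early HER2-positive (21.8 to 24.8) and 19.1 in the late HER2-positive library (17.9 to 20.3). The early over late ratio was 1.22 (1.11 to 1.34). Among alveolar type 2-like cells the ratio was 0.895 (0.779 to 1.03), from 14.1 and 15.8 CPM. Among mural-like cells the ratio was 1.04 (0.826 to 1.32), and among endothelial-like cells 1.21 (0.937 to 1.56). Levels differed more between classes than between libraries: alveolar type 1-like cells held 71.3 and 78.8 CPM in the early and late HER2-positive libraries, although their largest part was cluster 20 (62.9%, Zfp281 at 78.7 CPM) in the early and cluster 25 (55.2%, 33.2 CPM) in the late library. Mammary-like cells held 9.01 CPM (6.38 to 12.4), which was 0.451 of the level in the other late cells (0.317 to 0.624). Background barcodes held 29.5, 20.1 and 20.3 CPM of Zfp281 in the HER2-negative, early and late HER2-positive libraries.

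Nr2f1, a nuclear receptor gene linked to tumour cell dormancy (ENSMUSG00000069171, chromosome 13, 78188973 to 78199757), stood at 21.7 and 20.7 CPM in the early and late HER2-positive libraries, with a ratio of 1.05 (0.957 to 1.15). Its counts lay mainly in mural-like cells, at 148 CPM in the early HER2-positive, 233 in the late HER2-positive and 332 in the HER2-negative library. Bhlhe41 was near 1.5 CPM in both HER2-positive libraries, with a ratio of 1.04 (0.731 to 1.48). The mesenchymal regulators Prrx1 and Twist1 were 2.54-fold (2.30 to 2.82) and 2.63-fold (1.76 to 4.01) higher in the early library over all cells. Twist1 rests on 77 and 37 counts. In mural-like cells Prrx1 was 1.46-fold higher and Twist1 was at a ratio of 1.05 (0.506 to 2.21). In fibroblast-like cells Prrx1 was at 1.01 (0.717 to 1.44) and Twist1 at 0.979 (0.455 to 2.34). The largest part of these cells was cluster 8 in the early (48.6%) and cluster 21, with a median of 846 UMIs, in the late library (37.9%). Cdh11, a mesenchymal cadherin, was 2.80-fold higher over all cells, and its level in fibroblast-like cells was 319 CPM in the early and 358 CPM in the late HER2-positive library.

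**Figure D3:**
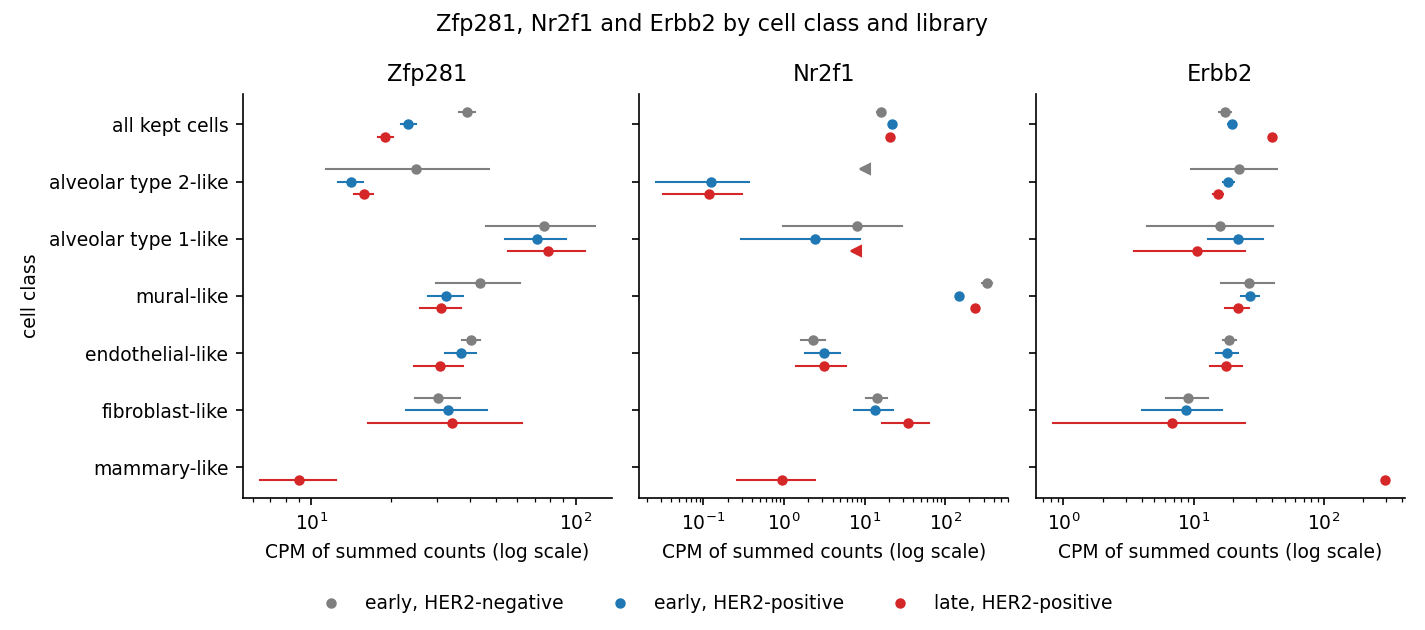
CPM of summed counts (x axes, log scale) of Zfp281, Nr2f1 and Erbb2 by class and library; points are single libraries, lines exact Poisson 95% intervals, and arrowheads the upper bound where the count was 0. Erbb2 stands apart in late mammary-like cells at 294 CPM, and Nr2f1 in mural-like cells.

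The early over late HER2-positive comparison over all kept cells asks how HER2-positive lung cells sorted at the early stage differ from those sorted when tumours are present. Most mesenchymal and immediate early genes were higher in early cells, and most G2 and M phase genes in late cells by summed counts. The libraries differ in their cell types, so these values mix the share of each class with the level in it. The median log2 ratio over all genes measured was 0.12, and list medians are read against it. The mesenchymal list had 24 of 27 members at least 1.5-fold higher in the early library, with a median of 1.09 at percentile 100 of random lists. The epithelial list had 5 of 23 members lower and 0 higher (median -0.37, percentile 0). The 5 became 8 under trimmed-mean scaling. Of the G2 and M phase list, 18 of 24 members were lower (median -1.12), a count that became 10 with equal weight per cell. Of the S phase list 5 of 24 were lower and 1 higher (median -0.12). The hypoxia and glycolysis list had 7 of 16 lower and 1 higher (median -0.53), with Egln3 at 0.0218 of the late level.

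The dormancy-associated list had 6 of 26 members higher and 2 lower, and its median of 0.06 lay at percentile 24.4. Its extremes were Tgfbr3 (2.26-fold) and Bmpr2 (2.08-fold) higher and Sox9 (0.225) and Igfbp5 (0.382) lower in the early library. The pluripotency-associated list had 3 higher and 3 lower of 8, with Klf4 2.01-fold higher and Myc at 0.622. Non-canonical Wnt genes had 3 higher and 1 lower of 13 (median 0.22), and canonical Wnt targets 3 higher and 0 lower of 11 (median -0.03). Dissociation and immediate early genes, which cell isolation itself can induce, were higher for 11 of 17 (median 0.75). Interferon response genes were higher for 6 of 15 (median 0.54) and MHC class I presentation genes for 3 of 12 (median 0.39). The basement membrane list had 6 higher and 1 lower of 19 (median 0.35), and the ErbB family list 2 higher and 3 lower of 10 (median -0.31). Leukocyte genes, a check of the CD45 sort, were higher for 7 and lower for 1 of 13 (median 1.27).

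Among the highest ratios over all cells, the matrix gene Mfap4 (ENSMUSG00000042436, chromosome 11, 61485431 to 61488900) was 6.02-fold higher in early cells (5.49 to 6.60). Inmt was 5.14-fold, Clec1a 4.62-fold, Pcolce2 4.04-fold, Car4 3.71-fold, Kdr 3.66-fold and Dcn 3.58-fold higher. Gimap6, Clec14a and Ogn completed the 10. The lowest ratios belonged to genes that lead the mammary-like cluster. Wfdc18 (ENSMUSG00000000983, chromosome 11, 83709015 to 83711348) had 0 early and 94707 late counts, at least 24948-fold lower in early cells, with the floor of 3 counts over the library. Csn3 had 0 and 87755 counts, at least 23116-fold lower, and Csn1s1 0 and 52899. Lalba had 4 and 18506 counts. Csn1s2a, Npy, Car6, Scgb2b27, Folr1 and Kcnn4 made up the rest. Epcam was at 177 CPM in early and 470 CPM in late cells, and at 208 CPM in late cells that were not mammary-like. Mki67 was at 3.64 CPM in early and 11.4 CPM in late cells, but at 1.17 CPM in late cells that were not mammary-like. Of the 145 early Mki67 counts, 106 lay in unnamed clusters.

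**Figure D4:**
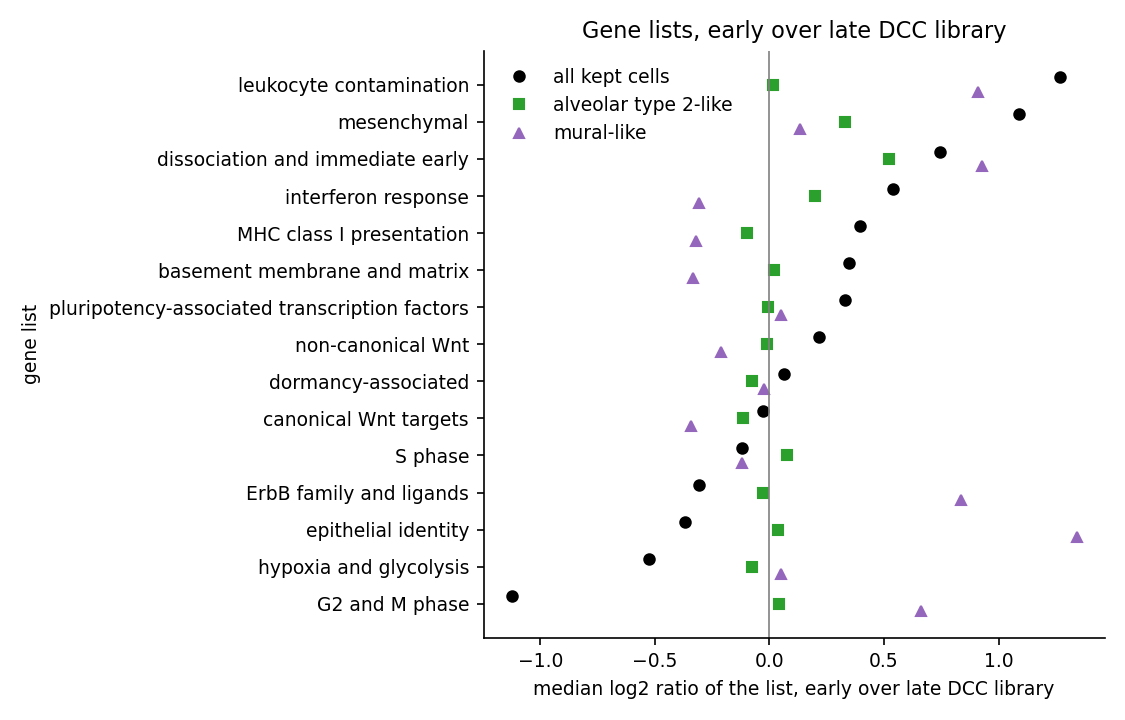
Median log2 ratio of early over late HER2-positive library (x axis) for each of the 15 gene lists, over all kept cells (circles), in alveolar type 2-like cells (squares) and in mural-like cells (triangles). The mesenchymal median of 1.09 over all cells is 0.33 in alveolar type 2-like and 0.13 in mural-like cells.

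Within alveolar type 2-like cells, the largest class, the early and late HER2-positive libraries were more alike. These cells make surfactant, and cluster 2 held the largest part of them in both libraries (30.8% and 36.0%). Of the epithelial list 0 of 23 members differed by 1.5-fold. Of the mesenchymal list 7 of 21 were higher and 2 lower, a count of higher members that was 1 after background was taken off and 12 without a count minimum. The dissociation list had 5 of 17 higher (median 0.52, percentile 100), a count that was 3 under trimmed-mean scaling and 9 with equal weight per cell. Cluster 14, with Fos at 1155 CPM against 279 in cluster 2, held 11.4% of early and 2.41% of late alveolar type 2-like cells. Within clusters 2, 3, 4, 12, 14 and 22 the dissociation list had 2, 4, 1, 8, 2 and 4 of 17 higher. The medians were 0.20, 0.35, 0.19, 0.57, 0.20 and 0.30. In clusters 4, 14 and 22, 1, 2 and 2 members were lower. Cluster 12 held 11.7% of early and 3.76% of late alveolar type 2-like cells. The dormancy-associated list had 2 of 22 higher and 1 lower (median -0.08). The stress-induced transcription factor gene Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039) was 2.37-fold higher (2.19 to 2.58), Dusp1 1.83-fold, Jund 1.53-fold and Jun 1.52-fold. Pim3, Gadd45b, Cirbp, Ier3, Ppp1r15a and Nr1d1 lay between 1.52-fold and 1.78-fold.

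On the lower side, the resistin-like gene Retnla was at 7.07 CPM in early and 168 CPM in late alveolar type 2-like cells, a ratio of 0.0421 (0.0359 to 0.0491). Its late counts came from 143 cells, with 26.5% in 1 cell. Background barcodes held 10.9 CPM of Retnla in the early and 145 CPM in the late library, near the levels in these cells. At the same late background, mural-like, endothelial-like and mammary-like cells held only 4.25, 2.40 and 0.949 CPM of Retnla. The secretoglobin gene Scgb1a1 was at 0.334 of the late level, with background barcodes at 10830 and 14534 CPM. Ost4, Snrpf, Sdhd and Ndufa1, which serve protein glycosylation, splicing and respiration, were at 0.380, 0.472, 0.496 and 0.536. Ptgs2, the prostaglandin synthase gene, was at 0.422 (0.401 to 0.443). Thbs1 was at 0.552, a log2 ratio of -0.86 that became 0.28 when called doublets were kept. Acta1 and Hbb-bs had 99.8% and 98.9% of their late counts in 1 cell, and without the cell with most counts the log2 ratio of Acta1 went from -8.90 to 0.12.

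Mural-like cells, which wrap small vessels, had more immediate early transcripts in the early than in the late HER2-positive library. Cluster 5 held 47.6% of them in the early and 70.8% in the late HER2-positive library, and cluster 11, led by smooth muscle genes, and cluster 13, led by Rgs5, held most of the rest. The dissociation list had 12 of 17 members higher in the early library (median 0.93, percentile 100), with Atf3 3.56-fold (3.12 to 4.07) and Egr1 2.82-fold higher. Fos stood at 103 CPM in cluster 5 and at 1628 and 1043 CPM in clusters 11 and 13, so these values mix cluster shares with levels. Within clusters 5, 11 and 13 the list had 9, 2 and 12 of 17 higher (medians 0.67, 0.33 and 0.80). Gadd45b, Fabp5 and Nr1d1 were 3.41-fold, 3.40-fold and 3.27-fold higher. Tcf21, a mesenchymal transcription factor gene (ENSMUSG00000045680, chromosome 10, 22817281 to 22820174), was at 55.6 CPM in early and 232 CPM in late cells, a ratio of 0.239 (0.210 to 0.273). HER2-negative mural-like cells held 110 CPM of Tcf21. The gene was also lower in early than in late fibroblast-like cells, at 165 and 443 CPM, so the difference is not limited to mural-like cells. In mural-like cells Gatm was at 0.318 of the late level, Serpina1b at 0.385, Col5a3 at 0.396 and Nck2 at 0.398. The Wnt target genes Lef1 and Axin2 were at 0.540 and 0.489, and Nr2f1 at 0.634. The matrix gene Spp1 was at 0.416, with 13060 CPM in cluster 5 and 47.7 and 85.6 CPM in clusters 11 and 13. The basement membrane and matrix list had 3 higher and 3 lower of 19 members (median -0.33). Epithelial genes were higher for 16 of 20 members, but for 6 with a minimum of 1000 UMIs per cell and for 7 with a minimum of 50 counts. Cluster 13, with 48445 CPM of Sftpc against 5982 in cluster 5, held 27.3% of early and 11.8% of late mural-like cells. Within clusters 5, 11 and 13, epithelial genes were higher for 1 of 9, 3 of 12 and 13 of 17 measured, and lower for 2, 1 and 0. Scgb1a1 was 8.63-fold higher in early mural-like cells, with 51.6% of its early counts in 1 cell. The G2 and M phase, ErbB family and leukocyte lists rested on at most 7 measured members here, and the sign of each median changed under at least 1 alternative.

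In endothelial-like cells, different clusters held the largest part in the early (cluster 1, 32.1%) and late (cluster 15, 26.4%) HER2-positive libraries. Sox18, an endothelial transcription factor gene (ENSMUSG00000046470, chromosome 2, 181669836 to 181671640), was at 62.2 CPM in early and 486 CPM in late cells, a ratio of 0.128 (0.114 to 0.144). It was seen in 312 of 1593 early and 396 of 497 late cells. HER2-negative endothelial-like cells held 61.8 CPM. St8sia4, Ier3, Plscr2 and Lrg1 were 2.61-fold, 2.57-fold, 2.55-fold and 2.45-fold higher in early cells, and Fabp4 was 11.2-fold higher from 41 early cells. Lyz2, Cxcl15 and Lyz1, genes of alveolar type 2 cells, were at 0.134, 0.146 and 0.157, well under their background levels in both libraries. Hbb-bs had 99.1% of its late counts in 1 cell.

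The early HER2-positive over HER2-negative comparison holds stage and age fixed and asks what the HER2 sort separates. Over all cells, most genes of the epithelial list were higher on the HER2-positive side, and most MHC class I presentation and interferon response genes on the HER2-negative side. The median log2 ratio over all genes was -0.37. Secretoglobins led, with Scgb1a1 405-fold (354 to 466) and Scgb3a2 at 7362 against 2 counts, followed by Cyp2f2 (122-fold), Hp, Lyz1, Scgb3a1, Lyz2, Chia1, Acoxl and Sftpa1. The epithelial list had 21 of 23 members higher and 2 lower (median 4.15), and the ErbB family list 8 of 9 higher (median 1.94). MHC class I presentation genes were lower for 12 of 12 members (median -1.74) and interferon response genes for 13 of 15 (median -1.68). These values mix the share of each class with the level in it: within endothelial-like cells 0 of 12 and 1 of 14 were lower (medians -0.14 and -0.03). The mesenchymal list had 16 of 27 lower and 5 higher, with a median of -0.71 that became 0.18 with equal weight per cell. The dormancy-associated list had 13 of 26 lower and 6 higher (median -0.52), and the G2 and M phase list 14 of 22 higher and 3 lower (median 1.11). The lowest ratios were those of Hbb-bt, Hbb-bs, Hba-a1, Slc7a10 (0.0612), Hmcn1 (0.0784), Figf, Scube2, Ackr3, Cdh11 (0.108) and Tmem252.

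Within classes, the Erbb2 ratio of HER2-positive over HER2-negative early cells was 1.02 in mural-like (0.630 to 1.74), 0.961 in endothelial-like (0.761 to 1.20) and 0.835 in alveolar type 2-like cells (0.420 to 1.95). The last rests on 8 counts in 51 HER2-negative cells, whose largest part was cluster 14 (27.5%), not cluster 2. Erbb2 levels in these classes, such as 27.2 CPM in early HER2-positive mural-like and 18.1 CPM in endothelial-like cells, lay near those of background barcodes, at 14.7, 21.9 and 34.1 CPM in the HER2-negative, early and late HER2-positive libraries. Zfp281 was at 0.914 in endothelial-like (0.779 to 1.07) and 0.741 in mural-like cells (0.503 to 1.12). Nr2f1 was at 0.446 in mural-like cells (0.385 to 0.518). Cluster 5 held 70.9% of HER2-negative and 47.6% of early HER2-positive mural-like cells, so ratios in this class mix cluster shares with levels. In endothelial-like cells Hmcn1, a basement membrane gene, was at 0.361 (0.341 to 0.381) and the histone gene Hist1h4d at 0.387. Sftpc was 15.3-fold higher there, at 2462 CPM. Background barcodes held 145940 CPM of Sftpc in the early HER2-positive and 9726 CPM in the HER2-negative library. The endothelial-like level was 1.69% and 1.66% of that background in the same order. The Sftpc ratio thus cannot be told apart from the difference in background. Lyz1, Scgb1a1, Sftpb and Sftpa1 followed Sftpc in rank. The haemoglobin genes Hbb-bt, Hbb-bs and Hba-a1 were lower. With 10% background taken off, their log2 ratios were 1.41 each with both libraries at the floor of 3 counts, which shows no direction. Background barcodes held 16863 CPM of Hbb-bs in the HER2-negative and 245 CPM in the early HER2-positive library. In mural-like cells the matrix gene Dcn was at 0.0169, from 15 against 118 counts. Scgb1a1, Lyz1, Lyz2, Scd1 and Slc34a2 were higher.

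Cells with proliferation transcripts after thinning to 1000 UMIs were 0.186% of HER2-negative (0.0927 to 0.332), 0.323% of early HER2-positive (0.205 to 0.484) and 0.555% of late HER2-positive cells (0.382 to 0.778). Of the 33 such late cells, 20 were mammary-like, a class with no early cells. The intervals of the HER2-positive libraries overlap, and with 1 gene fewer the order turned to 1.84% and 1.75%. Unthinned shares were 5.59%, 8.63% and 15.3%. Thinning left out 335, 355 and 109 shallower cells. Cells with at least 2 epithelial and 2 mesenchymal genes were 2.18%, 3.03% and 1.34% after thinning and 15.9%, 26.2% and 28.7% before it. The order of the HER2-positive libraries differs between these, and doublets were treated unevenly, so no order is read from them.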

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

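Both tests in this part were written down before their results were seen. Milk protein transcripts were found in barcodes that no comparison uses. Background barcodes, those with 1 to 100 UMIs, held 134 UMIs of milk protein genes in the early HER2-positive library and 102 in the early HER2-negative library, above the limit of 3 counts. Neither library has mammary-like cells, and their kept cells held 14 and 13 such UMIs, or 0.351 and 0.621 CPM. Of the 14, 10 lay in 1 cell of an unnamed cluster.

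Free milk protein RNA in the early lungs would spread over background barcodes as other RNA does, but only 4.48% of these UMIs (6 of 134) in the early HER2-positive library lay outside the barcodes of late mammary-like cells, which argues against it. An exchange of barcodes between libraries may be the source: 95.5% of the UMIs (128 of 134, 90.5 to 98.3) lay on barcodes that are mammary-like cells in the late library, which hold 0.111% of all background UMIs. In the early HER2-negative library 96 of 102 did, or 94.1%, against 0.160% of all background UMIs. Over all barcodes, the early HER2-positive library held 149 milk protein UMIs and the HER2-negative library 115. These equal 0.0777% and 0.0600% of the milk protein UMIs in kept cells of the late library. Whether the exchange arose in sequencing or in library handling was not tested, and a few UMIs from cells of the early lungs stay open.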

How the results depend on the processing

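The alternatives that removed the highest-scoring doublet share in all libraries, left out alveolar type 2 marker genes, or left out the cell with most counts of a gene were chosen after the results were seen; the others were planned. No paired analysis was possible because each group has 1 library. Over all alternatives, 153 of 216 shares stayed within their interval (46 of the others moved down), 310 of 360 list counts within 1.5 times, 2332 of 2763 gene ratios within their interval and 579 of 600 list medians close to the reported value, while 12 gene ratios and 5 medians reversed. Some of the reversed gene ratios rest on the floor of 3 counts, as stated below. The Zfp281 ratio of early over late HER2-positive cells stayed between 0.17 and 0.33 on the log2 scale under the alternatives run, and the mammary-like share between 3.20% and 3.32%. For the changes below the cause was not tested, except that thinning and gene thresholds act by construction. Cells were clustered and named anew where the cells, the resolution or the variable genes changed. The 58 late barcodes restored with called doublets are too few to take the late alveolar type 2-like share from 63.6% to 53.9%. That drop, and those at resolution 0.5, where the cells are the same, thus came with changed clusters or names. With 1000 UMIs, alveolar type 2-like cells were 49.1% of the early library, endothelial-like cells 18.1% of the early and 7.21% of the late, 6 epithelial genes were higher in mural-like cells, and in those cells the G2 and M phase median (-0.11), Cdh1 (-0.26) and Mki67 (-0.18) reversed. Under 10% mitochondrial, early shares were 43.6% alveolar type 2-like, 22.5% endothelial-like and 22.0% mural-like, late shares 61.8% alveolar type 2-like and 17.8% mural-like, and 3 dissociation genes were higher in alveolar type 2-like cells. With called doublets kept, alveolar type 2-like shares were 39.6% and 53.9%, the early endothelial-like share 20.0%, 9 dissociation genes were higher in alveolar type 2-like cells, the early mixed-identity share was 4.68%, and Thbs1 in alveolar type 2-like cells (0.28) and Hbb-bs (0.66) and Cdh1 (0.67) in endothelial-like cells reversed. That setting left under 50 alveolar type 2-like HER2-negative cells, so this class gave no value there. With the highest-scoring share removed in all libraries, endothelial-like shares were 17.1% and 7.29%. With 1000 variable genes 7 of 24 shares moved, all down, among them alveolar type 1-like and fibroblast-like cells in every library. At resolution 0.5, alveolar type 2-like shares were 40.5% and 52.5%. Trimmed-mean scaling gave 8 epithelial genes lower over all cells and 3 dissociation genes higher in alveolar type 2-like cells. Equal weight per cell gave 10 G2 and M phase genes lower and 9 dissociation genes higher in alveolar type 2-like cells, and reversed the mural-like ErbB median (-0.0203) and Mki67 (-0.26) and the mesenchymal median over HER2-negative cells (0.18). With 10% background off, 1 mesenchymal gene was higher in alveolar type 2-like cells. Hbb-bt, Hbb-bs and Hba-a1 in endothelial-like cells over HER2-negative ones went to 1.41 each, with both libraries at the floor of 3 counts. These reversals show no direction. A minimum of 50 counts gave 4 mesenchymal genes higher in alveolar type 2-like cells, 7 epithelial genes in mural-like cells, and an ErbB median of -0.0826 there. No minimum gave 12 mesenchymal genes in alveolar type 2-like cells and a leukocyte median of -0.34 in mural-like cells. Without the cell with most counts, Acta1 in alveolar type 2-like (0.12), Mki67 in mural-like (-0.34) and Hbb-bs in endothelial-like cells (1.70) reversed. The early count of Acta1 and both counts of Mki67 were then at the floor of 3, so those reversals show no direction. Proliferation shares (early, late) were 0.187% and 0.281% at 500 UMIs, 1.05% and 1.29% at 2000 UMIs, 1.84% and 1.75% with 1 gene fewer, and 0.155% and 0.353% with 1 more; mixed-identity shares were 0.816% and 0.297%, 9.23% and 5.56%, 31.0% and 25.1%, and 0.323% and 0.134% in the same order.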

Other observations

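Of the tests in this part, those of depth at the lower quartile, of free RNA in the late library, of free surfactant RNA and of Erbb2 in alveolar type 1-like or fibroblast-like cells were chosen after the results were seen.

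Mammary-like cells were found in the late but not in the early HER2-positive library. Loss of such cells through lower depth is argued against: when late mammary-like cells were thinned to 1000 UMIs, 92.7% (179 of 193) kept at least 3 mammary markers, with a lower bound of 88.1% that misses the 90% set in advance, and when thinned to 2944 UMIs, the lower quartile of early HER2-positive cells, 97.9% did (184 of 188, 94.6 to 99.4). Removal by the barcode filters is argued against by 0 of 4062 removed early barcodes with at least 100 UMIs that held 5 mammary markers. The most markers in 1 of these barcodes was 4, and together they held 1 milk protein UMI. Shallow cells stay open, since late mammary-like cells were not thinned below 1000 UMIs or checked for 5 markers. Free RNA in the late library as the content of these barcodes is argued against by mesenchymal list genes that no marker table holds: their median level in mammary-like cells was 0.0473 of that in background barcodes (quartiles 0.0285 and 0.124), and 13 of 14 had an upper bound under 0.5. Sftpc stood at 7478 CPM in mammary-like cells against 162883 CPM in background. A difference of stage, age or animal stays open as an untested biological hypothesis, and cancer cells that express none of the mammary markers could be present in either library without being named.

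Lung cell types made up most of both HER2-positive libraries. Sftpc itself cannot tell alveolar type 2-like cells from free surfactant RNA, since it names them and stood at 227137 CPM in them against 145940 CPM in background barcodes of the early HER2-positive library, and at 223155 against 162883 CPM in the late one. Barcodes without a cell, or stromal cells, filled with such RNA are argued against by the same mesenchymal genes, whose median ratio to background was 0.0209 in early and 0.0336 in late alveolar type 2-like cells, with upper bounds under 0.5 for 13 and 12 of 14. The same ratios argue against other epithelial cells with free surfactant RNA, since free RNA would bring these mesenchymal genes along. Free RNA of another make-up than that of background barcodes was not tested. Higher counted Erbb2 mRNA in the sorted cells of a class is argued against by the mural-like ratio of 1.02, with an upper bound of 1.74, and the upper bound in endothelial-like cells (1.20) was also under 2. The cluster mix of mural-like cells differs between the early libraries, but Erbb2 was at 23.6, 28.3 and 23.3 CPM in clusters 5, 11 and 13. Erbb2 levels in mural-like and endothelial-like cells lay near those in background, but by their Sftpc at most 19.4% of HER2-negative and 17.3% of early HER2-positive mural-like UMIs, and 1.66% and 1.69% of endothelial-like ones, can come from background. In alveolar type 1-like cells (1.36, 0.448 to 5.52, from 18 and 4 counts) and fibroblast-like cells (0.968, 0.405 to 2.08) too few counts keep it open. In alveolar type 2-like cells (0.835, 0.420 to 1.95) it is left open too, since the 8 HER2-negative counts come from 51 cells with another cluster mix. Whether transgene transcripts were counted as Erbb2 was not tested and stays open, because the 294 CPM in late mammary-like cells may come from the mouse gene, and a difference in uncounted transgene mRNA would not show in these ratios. HER2 protein and the sort gate may differ from mRNA, which the files cannot test, and a biological difference between the sorted fractions stays open.

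The genes Ost4 and Snrpf were lower in the early than in the late HER2-positive library in every named class with at least 50 cells in both, and are reported as values alone. Ost4 was at 47.9 CPM over early and 128 CPM over late cells, with background barcodes at 61.1 and 116 CPM. In ciliated airway-like cells Ost4 was at 72.0 and 221 CPM, and in endothelial-like cells at 64.3 and 186 CPM. Snrpf was at 39.3 CPM over early and 88.5 CPM over late cells, with background at 44.5 and 65.6 CPM. Retnla was at 7.88 CPM in early and 1663 CPM in late airway secretory or basal-like cells, from 4 and 1750 counts, of which the late ones lay in 16 of 78 cells, with 55.9% in 1 cell.

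Some small unnamed clusters had cells in every library. Cluster 31, led by Top2a and Ube2c, held 2 HER2-negative, 12 early HER2-positive and 6 late HER2-positive cells. Cluster 32, led by the cartilage collagen gene Col2a1, held 1, 12 and 7 cells. Cluster 28, led by Cxcl13, held 38, 29 and 24 cells. These clusters were chosen after their values were seen.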
